A study of Mus musculus with 4 samples.

How the data were processed

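Poly(A)-selected RNA from spinal cord mononuclear cells of EAE mice, isolated on a Percoll gradient, was sequenced on an Illumina instrument, per the labels' protocols. Per the submitters' processing notes, the tools were bcl2fastq, STAR 2.5.3a and DESeq2, and the genome build was mm10. The read counter, annotation release, use of strand and any filter are not given in the sources used here. The deposited table holds log2 values for 32246 genes in 4 libraries, the authors' group means on the log2 scale, a log2 fold change (the ratio of P155 to Scr), and a p-value and FDR of the authors' own comparison, whose test the deposited table does not name. Undoing the log2 and the added 1 left whole multiples of 1 step per library, so that reads per gene could be recovered. In all libraries 100% of the values were whole within a tolerance of 1e-06. The steps are the reciprocals of median-of-ratios size factors of 1.23 in Scr replicate 4, 1.19 in Scr replicate 5, 1.19 in P155 replicate 4 and 0.592 in P155 replicate 5. P155 replicate 5 had the fewest reads, 30777600, so its values carry more counting error. Symbols of 25 genes that spreadsheet software had turned into dates were restored by gene identifier where a name was found, and 32168 identifiers matched GENCODE M21, which uses the same build.

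The plan, gene lists and rule for named genes were fixed before the data were examined. The plan named edgeR for raw counts, which was not run, and limma for normalized values, which was used because the values are on the log2 scale. Genes with a normalized value of at least 1 in at least 2 libraries were kept, 27079 in all, and P155 was compared with Scr by limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(value + 1), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Fold changes on this scale understate the change of genes at low levels. For 43 lists with at least 4 tested members, camera was run with a preset correlation of 0.01, and again with an estimated correlation and with fry. With the preset, the genes of a list count as nearly independent, so these p-values do not measure the spread between libraries. Named genes were those with the smallest unadjusted p in each direction, up to 5 each because no gene passed, with libraries of the groups not overlapping and a mean normalized value of at least 5 in the higher group, leaving out deposited symbols of predicted genes, RIKEN clones, pseudogenes and antigen receptor segments. The second Map2k7 identifier was kept by its deposited symbol, although GENCODE M21 gives it a predicted gene's name. To these were added up to 4 genes with the smallest p of each list that passed and a fixed set including Mir155hg, Hspa8 and H2-Aa. Other genes, such as Zbtb9, were chosen after their values were seen. An item that the rule names is not reported here. The enrichment of the authors' calls was tested by Fisher's exact test against 18528 genes whose higher group mean was at least that of the lowest called gene.

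Both tests were tried on simulated data with the depth of these libraries and 1 trimmed spread shared by genes of similar level. In a run on 26236 genes for P155 against Scr, limma recovered 27.9% of genes changed by 1 log2 unit. It recovered 78.8% at 2 units and 92.4% at 3 units, with 0 other genes called. The simulation lacked differences in spread between genes of similar level, so these shares do not give the power in these data. Zfp180, with a log2 difference of -2.74 between P155 and Scr, had limma adjusted p = 0.661. In 20 simulated draws of the same comparison on 27079 genes, a list shifted by -1 passed camera with the preset correlation in 20 draws. With the estimated correlation it passed in 0 draws, so that setting missed a true shift at this number of libraries. The simulated genes were independent, so a true correlation between genes was not what made that setting miss. Genes were simulated as independent, with the extreme spread trimmed, so real lists, whose genes move together, can pass the preset correlation more often. Alternatives were the number shared by the labels as a block, each library left out in turn, with the lone library of an arm assumed to vary like the other arm, scaling by library size only, no filter, a stricter filter (a CPM of at least 1 in at least 2 libraries and a mean of at least 50 reads), a pseudocount of 0.1, a robust variance prior, limma-voom on the recovered reads, a test against a fold change of 1.5, a threshold of 0.1, camera on ranks and lists without shared genes. Quantile normalization, thinning of reads to the shallowest library, voom weights for the lists and a pan-leukocyte reference were chosen after seeing the data. The DESeq2 test, planned for a table of counts, was not run, and limma-voom was the test applied to the recovered reads, while median-of-ratios scaling is the deposited scale itself. Coordinates are from GENCODE M21.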

Results

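RNA sequencing was carried out on mononuclear cells isolated from the spinal cord of C57BL/6 mice with experimental autoimmune encephalomyelitis (EAE), an immune-mediated model of multiple sclerosis. The mice received either a scramble micropeptide (Scr) or microPEP155 (P155), given on alternate days starting on day 8 after immunization. P155 is a short peptide encoded by the transcript Mir155hg, and it is known to bind the chaperone HSC70, the product of Hspa8. There were 4 libraries, 2 Scr and 2 P155, numbered 4 and 5 in each group. The reads behind the table, rounded, amounted to 63875400 in Scr replicate 4, 64702900 in Scr replicate 5, 63862700 in P155 replicate 4 and 30777600 in P155 replicate 5, and 24409 to 28432 genes had at least 1 read. Levels are given as log2(normalized reads + 1), with the SD and n = 2 per group. The labels do not state that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical.

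The comparison of P155 with Scr asked which transcripts of these spinal cord cell preparations differed after treatment with the peptide. Neural transcripts such as Mbp were abundant in all libraries, so the samples held a mix of neural and immune RNA rather than the infiltrate alone. Gene lists were tested with camera at a preset correlation. Marker genes of B cells, monocytes, neutrophils, mast cells, T cells and dividing cells lay lower on average in the P155 libraries. Genes of cholesterol synthesis and neuron markers lay slightly higher on average. For neutrophil, T cell and neuron markers the list means of the groups overlapped. P155 replicate 5 lay above Scr replicate 5 for neutrophil markers, and P155 replicate 4 above Scr replicate 4 for T cell markers. None of these list calls held with the correlation estimated from these libraries (camera adjusted p = 0.599 with an estimated correlation) or with fry. The estimated correlation also missed a simulated shift, so its loss alone cannot decide on these calls. Camera with the preset counts the genes of a list as nearly independent, so its p-values do not measure the spread between libraries. No single gene passed the test across all genes. Of 27079 genes tested with limma, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.368. At an unadjusted p under 0.05 there were 1179 genes, against 1354 expected by chance. Grouping the libraries by replicate number instead of treatment gave 1867 genes at that threshold. Setting Scr replicate 4 and P155 replicate 5 against the others gave 739. For P155 against Scr, limma-voom on the recovered reads gave 0 genes after adjustment and 1072 at the unadjusted threshold. Without P155 replicate 4 the count became 6 genes, all lower in P155, which were chosen after their values were seen. They were a second identifier of Map2k7 and 5 genes that were low in P155 replicate 5 alone: Gm6977, Zbtb9 and AC154550.1, listed at 0 there, Rsc1a1 at 4.41 and Ldlrad3 at 5.38. In P155 replicate 4 these 5 genes stood between 9.48 and 10.56.

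The genes with the smallest p in each direction had differences several times their standard error without passing adjustment. Sar1a, a GTPase of vesicle budding from the endoplasmic reticulum (ENSMUSG00000020088, chromosome 10, 61680299 to 61693297, plus strand, mm10), stood at 10.60 ± 0.14 in Scr and 12.63 ± 0.05 in P155, a log2 difference of 2.03 (SE 0.16, limma adjusted p = 0.577). Ndufaf4, an assembly factor of respiratory complex I (ENSMUSG00000028261, chromosome 4, 24898083 to 24905001), stood at 8.47 ± 0.19 in Scr and 10.83 ± 0.21 in P155 (limma adjusted p = 0.697). Pafah1b1, which encodes the dynein regulator LIS1, was at 12.92 ± 0.50 in Scr and 14.84 ± 0.04 in P155, and the X-linked zinc finger gene Zfx was at 8.53 ± 0.40 and 10.34 ± 0.17. Pp2d1 was listed at 0 in both Scr libraries and at 4.23 and 4.81 in P155 replicates 4 and 5. In the other direction, Zfp180, a zinc finger gene on chromosome 7 (24081924 to 24107713), stood at 10.84 ± 0.14 in Scr and 8.10 ± 0.27 in P155, a log2 difference of -2.74 (SE 0.23, limma adjusted p = 0.661). E2f3, a transcription factor of the cell cycle, was at 10.21 ± 0.06 in Scr and 8.39 ± 0.12 in P155, Rbm12b1 at 9.62 ± 0.26 and 7.45 ± 0.02, and Zmym1 at 10.04 ± 0.09 and 8.22 ± 0.16, each with limma adjusted p = 0.861. A second identifier of the kinase gene Map2k7 (ENSMUSG00000109061, named Gm49320 in GENCODE M21) was at 9.38 and 8.62 in Scr replicates 4 and 5 and at 0 in both P155 libraries. It spans 4238865 to 4251423 on chromosome 8 and overlaps the first Map2k7 identifier, at 4238740 to 4247897 on the same strand, so reads from these genes cannot be assigned with certainty. The first identifier stood at 10.02 and 9.16 in Scr replicates 4 and 5 and at 10.93 and 11.87 in P155 replicates 4 and 5, the opposite direction (limma adjusted p = 0.861).

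**Figure D1:**
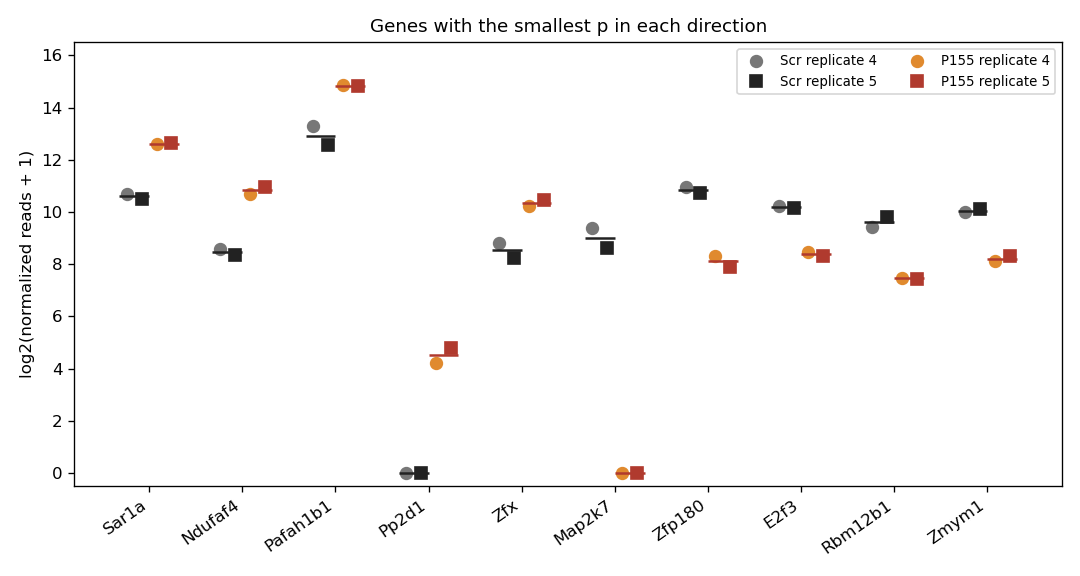
Levels, as log2(normalized reads + 1), of the 5 genes with the smallest p in each direction, with 1 point per library and a line at each group's mean. Sar1a lies at 10.50 to 10.70 in the Scr libraries and 12.59 to 12.66 in the P155 libraries, and none of these genes passed adjustment.

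The authors' deposited table called 171 genes at an FDR under 0.05, 55 higher and 116 lower in P155, by a test the table does not state. The authors' deposited table gives Ccr2, the chemokine receptor of inflammatory monocytes, an FDR of 0.00132 and a log2 fold change of -1.29. Of 18 B cell markers in the background, the authors' deposited table called 5 lower, against 116 of all 18528 background genes (Fisher's exact test, one-sided, adjusted p = 6.09e-06). For cell cycle genes the share in the authors' deposited table was 5 of 33 (adjusted p = 7.83e-05, Fisher's exact test). Border-associated macrophage markers had 3 of 12 (adjusted p = 0.00145), monocyte genes 3 of 21 (adjusted p = 0.0063) and meningeal fibroblast markers 2 of 13 (adjusted p = 0.0498, Fisher's exact test) called lower in the authors' deposited table. These lists were fixed beforehand, and 86 such tests were made. Fisher's test counts genes as independent draws, while genes of a list can move together in the same 4 libraries. These p-values therefore do not measure the spread between libraries. By camera with an estimated correlation, which also missed a simulated shift, each of these lists had adjusted p = 0.599.

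Genes of dividing cells and of B cells were lower in P155 as groups. In the cell cycle list, 32 of 33 genes were lower in P155, with a median log2 difference of -0.91 (camera adjusted p = 3.9e-13). That call was lost with the correlation between genes estimated from these libraries (adjusted p = 0.599 with an estimated correlation), a setting that also missed a simulated shift. The mitotic kinase gene Cdk1 stood at 8.17 ± 0.02 in Scr and 7.02 ± 0.17 in P155, the kinase gene Plk1 at 7.91 ± 0.25 and 6.66 ± 0.19, and the cytokinesis motor gene Kif23 at 8.04 ± 0.10 and 6.87 ± 0.15. Both P155 libraries lay below both Scr libraries in 28 of the 33 genes, where chance gives 16.7% in this direction for 1 gene. Genes of this list move together (estimated correlation 0.265), so the 28 genes are not separate evidence and the share cannot be set against 16.7%. Of B and plasma cell markers, 16 of 19 were lower, with a median of -1.01 (camera adjusted p = 1.53e-06, and adjusted p = 0.599 with an estimated correlation). The B cell receptor regulator Cd22 stood at 10.02 ± 0.67 in Scr and 8.56 ± 0.23 in P155, and the immunoglobulin D heavy chain gene Ighd at 8.80 ± 0.75 and 7.14 ± 0.23. No gene of either list passed adjusted over the list alone, and 0 passed over all genes by limma, with 15 and 10 at an unadjusted p under 0.05.

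Myeloid and granulocyte genes were lower as groups, with libraries that disagreed for the granulocytes. Of 21 genes of infiltrating monocytes and macrophages, 18 were lower (median -0.81, camera adjusted p = 7.52e-06, and adjusted p = 0.599 with an estimated correlation). Ccr2, at 10.45 ± 0.34 in Scr and 9.16 ± 0.33 in P155, and the coagulation factor gene F13a1, at 10.55 ± 0.08 and 9.75 ± 0.07, fell in the test adjusted over the list alone, and 0 genes passed over all genes. All 18 neutrophil markers were lower, with a median of -1.36 (camera adjusted p = 5.32e-06, and adjusted p = 0.599 with an estimated correlation), yet the call was lost without Scr replicate 4 (median -0.56, adjusted p = 0.119) and without P155 replicate 4 (median -0.30, adjusted p = 0.0824). Without Scr replicate 5 the median was -2.23 and without P155 replicate 5 it was -2.44. The mean of this list, relative to its mean over all libraries, was 1.51 in Scr replicate 4, -0.03 in Scr replicate 5, -1.56 in P155 replicate 4 and 0.08 in P155 replicate 5. Platelet and erythroid markers had the same order of libraries, with 1.01 and 0.92 in Scr replicate 4 and -1.02 and -1.18 in P155 replicate 4. Both calls were lost with an estimated correlation (camera adjusted p = 0.599 and 0.613 with an estimated correlation), without Scr replicate 4 (camera adjusted p = 0.178 and 0.626) and without P155 replicate 4 (camera adjusted p = 0.327 and 0.438), where the erythroid median turned to 0.11. The 10 mast cell and basophil markers were all lower (median -1.87, camera adjusted p = 7.46e-05, and adjusted p = 0.599 with an estimated correlation), with the call lost without Scr replicate 4 (median -0.64, adjusted p = 0.377) and a median of -0.79 without P155 replicate 4. Of these, 3 genes at low levels passed adjusted over the list alone, the mast cell protease genes Cpa3, Mcpt4 and Tpsb2. Mcpt4 and Tpsb2 were listed at 0 in both P155 libraries.

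T cell and antigen presentation genes were lower in P155 on average, with the T cell genes at near equal levels in the replicates numbered 4. All 22 T cell markers were lower (median -0.73, camera adjusted p = 2.95e-05, and adjusted p = 0.599 with an estimated correlation), and the call was lost without Scr replicate 5 (median -0.24, adjusted p = 0.108), with a median of -0.38 without P155 replicate 5. The mean of this list was -0.08 in Scr replicate 4 and 0.02 in P155 replicate 4, against 0.81 in Scr replicate 5 and -0.74 in P155 replicate 5. Scr replicate 5 also had the highest mitochondrial share of reads, 12.05% against 8.54% to 9.68%, and the highest share taken by its top 10 genes, 12.7% against 8.92% to 9.96%. Cd3e, a chain of the T cell receptor complex, stood at 7.91 ± 0.51 in Scr and 7.32 ± 0.41 in P155, and Cd4 at 8.56 ± 0.75 and 7.89 ± 0.34. All 18 Th1 and cytotoxic genes were lower (median -0.89, camera adjusted p = 2.35e-05, and adjusted p = 0.599 with an estimated correlation), with Il18rap, a subunit of the interleukin-18 receptor, at 9.05 ± 0.40 in Scr and 7.86 ± 0.23 in P155. The 15 genes of MHC class II presentation were all lower (median -0.68, camera adjusted p = 6.12e-06, and adjusted p = 0.599 with an estimated correlation). The class II genes H2-Aa and H2-Ab1 stood at 14.36 ± 0.52 and 14.04 ± 0.56 in Scr and at 13.66 ± 0.49 and 13.34 ± 0.51 in P155, and the invariant chain gene Cd74 at 15.41 ± 0.38 and 14.75 ± 0.51, with limma adjusted p = 0.861 for each. H2-Aa was 13.99 in Scr replicate 4 and 14.01 in P155 replicate 4. Of 20 MHC class I genes, 18 were lower (median -0.56, camera adjusted p = 7.7e-05, and adjusted p = 0.599 with an estimated correlation), and without Scr replicate 5 the call was lost (median -0.22, adjusted p = 0.108).

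In the type I interferon response, 24 of 25 genes were lower (median -0.66, camera adjusted p = 2.32e-08, and adjusted p = 0.599 with an estimated correlation). The antiviral genes Rsad2, at 9.77 ± 0.34 in Scr and 8.54 ± 0.16 in P155, and Oas3, at 8.34 ± 0.13 and 6.86 ± 0.36, had the smallest p of the list. The mean of this list was 0.73 in Scr replicate 5, 0.02 in Scr replicate 4 and -0.15 in P155 replicate 4, and the median was -0.22 without Scr replicate 5 and -1.11 without Scr replicate 4. Of 83 genes of cytosolic ribosomal proteins, 80 were lower (median -0.40, camera adjusted p = 2.18e-11, and adjusted p = 0.599 with an estimated correlation), and the call was lost without Scr replicate 5 (median -0.05, adjusted p = 0.108). Ribosomal protein genes took 3.03% of the reads in Scr replicate 5 and 1.78% to 1.92% in the other libraries. The mean of this list was 0.58 in Scr replicate 5, against -0.14 in Scr replicate 4 and -0.25 and -0.18 in P155 replicates 4 and 5. Of 18 homeostatic microglia genes, 15 were lower (median -0.41, camera adjusted p = 0.002, and adjusted p = 0.599 with an estimated correlation). The microglial purinergic receptor gene P2ry12 was at 10.93 ± 0.06 in Scr and 10.10 ± 0.81 in P155, and Tmem119 at 11.55 ± 0.34 and 11.35 ± 0.04.

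The higher lists were few and small in size. Of 20 genes of cholesterol synthesis, 16 were higher (median 0.26, camera adjusted p = 1.93e-05, and adjusted p = 0.599 with an estimated correlation), among them Insig1, a sterol sensor of the pathway, at 11.80 ± 0.20 in Scr and 12.44 ± 0.10 in P155. Of 19 neuron markers, 16 were higher (median 0.28, camera adjusted p = 3.02e-04, and adjusted p = 0.599 with an estimated correlation), and the call was lost without Scr replicate 5 (median 0.08, adjusted p = 0.0714). Neuronal enolase, Eno2, stood at 14.65 ± 0.03 in Scr and 15.08 ± 0.05 in P155. Of 25 genes of HSC70 and other chaperones, 17 were higher by a median of 0.12 (camera adjusted p = 0.0104, and adjusted p = 0.599 with an estimated correlation), a call lost without P155 replicate 4 (adjusted p = 0.144) or P155 replicate 5 (adjusted p = 0.136). Hspa8 itself was 15.97 in both Scr libraries and 16.29 in both P155 libraries (limma adjusted p = 0.861). Oligodendrocyte and myelin genes were higher in 16 of 23 (median 0.09, camera adjusted p = 0.0359, and adjusted p = 0.599 with an estimated correlation), and the call was lost without Scr replicate 4 (adjusted p = 0.365), P155 replicate 4 (adjusted p = 0.165) or P155 replicate 5 (adjusted p = 0.217). Mbp, the myelin basic protein gene, stood at 16.36 ± 0.48 in Scr and 16.61 ± 0.21 in P155.

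**Figure D2:**
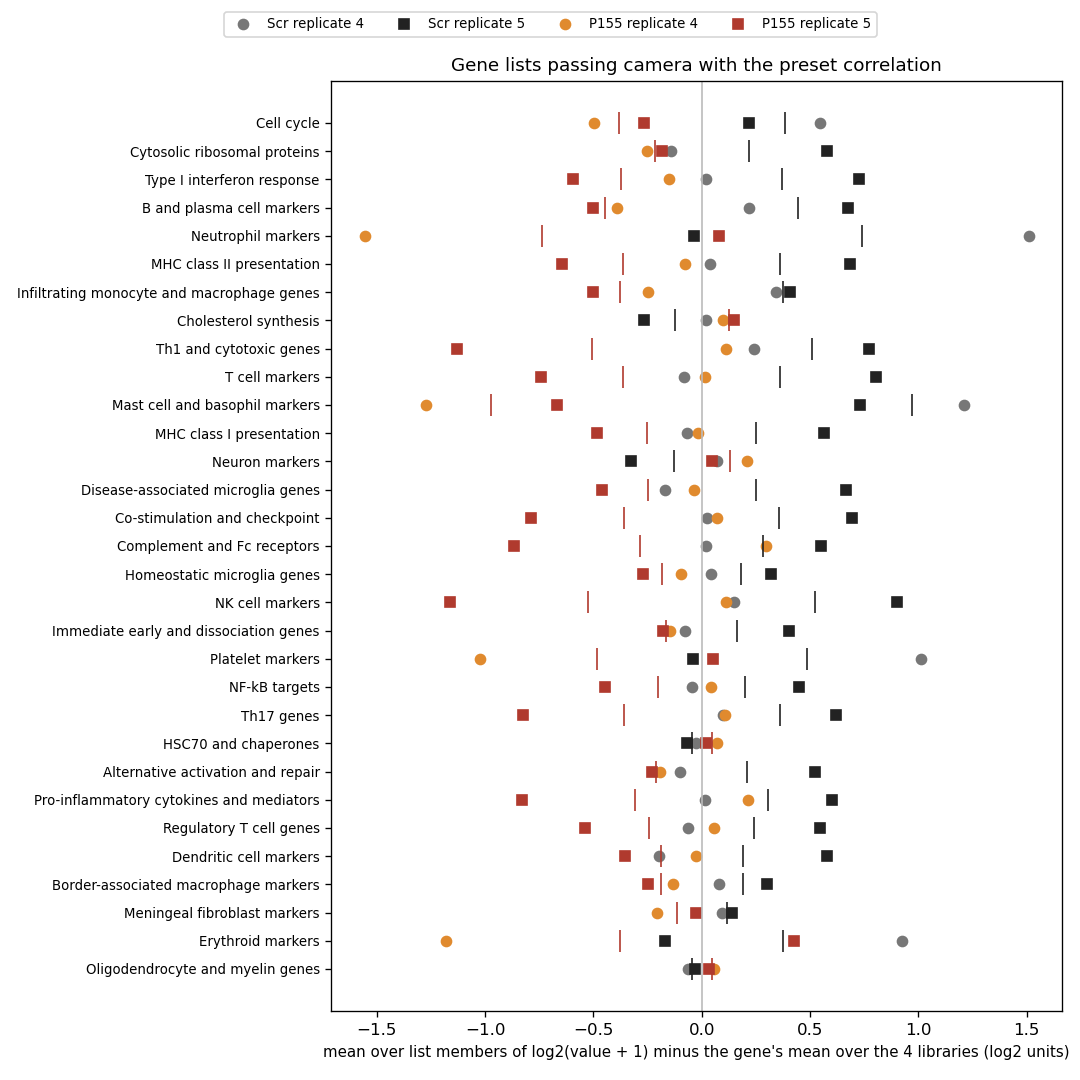
Gene lists that passed camera with the preset correlation, with 1 point per library for the mean over list members of log2(normalized reads + 1), relative to each gene's mean over the 4 libraries, and a bar at each group's mean. For T cell markers, Scr replicate 4 lies at -0.08 and P155 replicate 4 at 0.02, while Scr replicate 5 and P155 replicate 5 lie at 0.81 and -0.74.

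In all, 31 of 43 lists passed camera with the preset correlation, 27 lower and 4 higher in P155. With an estimated correlation 0 passed, and 0 passed with fry. The estimated correlation also missed a simulated shift in all 20 draws, so these losses do not tell a true shift from none. The simulated genes were independent, so losses with that setting cannot be read as an effect of correlation between genes. Fry was not tried on simulated data. For monocyte and macrophage genes the estimated correlation was -0.00136, below the preset 0.01, and the call was lost all the same. Chaperone, mast cell and oligodendrocyte genes also lay below the preset. Many other lists lay far above it, with 0.887 for T cell, 0.85 for ribosomal protein, 0.818 for MHC class II and 0.661 for type I interferon genes. There the preset counts genes that move together as nearly independent, so its p-values can be far too small. The preset correlation does not separate the treatment from other groupings of these libraries. In a split that ignores the treatment, Scr replicate 5 and P155 replicate 4 were set against Scr replicate 4 and P155 replicate 5. There 27 lists passed, 6 lower and 21 higher in Scr replicate 5 and P155 replicate 4. With the replicates numbered 4 set against those numbered 5, 3 passed. Of the 31 lists, 15 kept their call without Scr replicate 5, 25 without Scr replicate 4, 21 without P155 replicate 4 and 21 without P155 replicate 5. Lists that kept it without each library in turn were cell cycle, type I interferon response, B and plasma cells, MHC class II, monocytes and macrophages, cholesterol synthesis, Th1 and cytotoxic genes and homeostatic microglia. Most of these were smaller without a library: without Scr replicate 5 the medians were -0.22 for type I interferon, -0.30 for MHC class II, -0.53 for monocyte, -0.48 for Th1 and 0.11 for cholesterol genes. Without P155 replicate 5 they were -0.35 for MHC class II, -0.47 for monocyte, -0.53 for Th1 and -0.21 for microglia genes. The other lists lower in P155 were disease-associated microglia genes, co-stimulation and checkpoint genes, complement and Fc receptors, NK cell markers, immediate early genes, platelet markers, NF-kB targets, Th17 genes, alternative activation genes, pro-inflammatory mediators, regulatory T cell genes, and markers of dendritic cells, border-associated macrophages, meningeal fibroblasts and erythroid cells. Their medians ranged from -0.95 for platelet markers to -0.24 for meningeal fibroblasts, and none kept its call with an estimated correlation (adjusted p = 0.599 to 0.613 with an estimated correlation). Without Scr replicate 5 the median went from -0.56 to -0.03 for alternative activation, from -0.30 to -0.03 for dendritic cell, from -0.52 to -0.13 for disease-associated microglia and from -0.70 to -0.22 for co-stimulation genes. Without P155 replicate 5 it went from -0.54 to -0.15 for complement and Fc receptor genes and from -0.44 to -0.09 for regulatory T cell genes. It also went from -0.91 to -0.35 for NK cell and from -0.28 to -0.07 for border-associated macrophage markers. Without Scr replicate 5 it went from -0.39 to -0.14 for NF-kB targets and from -0.62 to -0.29 for pro-inflammatory mediators. For platelet markers it went from -0.95 to -0.55 without P155 replicate 4. Each of these was larger in size with another library left out. Markers of endothelial cells, pericytes, oligodendrocyte precursors, astrocytes and ependymal cells, and the lists of lysosome, chemokine, histone, mitochondrially encoded, oxidative phosphorylation, glycolysis and interferon gamma response genes did not pass. For oxidative phosphorylation and glycolysis the median and the mean of the members had opposite signs.

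Of inflammatory genes named in advance, none passed limma (adjusted p of at least 0.861). Tnf stood at 8.05 ± 0.78 in Scr and 7.21 ± 0.38 in P155, Il1b had means of 7.68 and 7.63, and Ifng stood at 4.10 ± 0.08 and 4.10 ± 0.59. The dendritic and myeloid integrin gene Itgax was at 11.58 ± 0.60 in Scr and 10.59 ± 0.72 in P155. Foxp3, the regulatory T cell transcription factor, was at 6.37 and 7.90 in Scr replicates 4 and 5 and at 7.33 and 3.24 in P155 replicates 4 and 5. Il17a was listed at 0 in Scr replicate 4 and P155 replicate 5 and at 1.82 in the other libraries. Mir155hg, the host gene of the peptide, was at 4.42 and 6.46 in Scr replicates 4 and 5, and at 0 and 4.81 in P155 replicates 4 and 5. Across 17053 well-expressed genes, which are not independent replicates, Pearson's correlation between libraries ranged from 0.934 to 0.975. It was highest between Scr replicate 4 and P155 replicate 4, was 0.947 within Scr and 0.959 within P155.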

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

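Quantile normalization, thinning and voom weights for the lists were chosen after seeing the data. The count of 0 genes by limma stayed at 0 under each alternative except 1 removal. With 1 library left out the counts ranged from 0 to 6 genes, from 0 to 0 higher and from 0 to 6 lower, and the 6 came without P155 replicate 4, where 5 of them rest on P155 replicate 5 alone. At an unadjusted p under 0.05 the count was 1179 with all 4 libraries. It fell without Scr replicate 5 or P155 replicate 5 and rose without Scr replicate 4 or P155 replicate 4. The list count of 31 became 0 (0 higher and 0 lower) for camera with an estimated correlation and 0 for fry, and the estimated correlation missed a simulated shift too. With 1 library left out it ranged from 17 to 28, from 3 to 4 higher and from 13 to 25 lower, the lowest without Scr replicate 5, and the cause was not tested. With quantile normalization 31 lists passed, 2 of them higher, of which 29 were among the 31 above, and the chaperone and oligodendrocyte lists no longer passed. With the replicate number as a block there were 0 genes, 32 lists, 4 of them higher and 28 lower, and the deviations of same-numbered libraries correlated at 0.0991 across genes. The erythroid list turned, at a median of 0.11 without P155 replicate 4 and from -1.41 to 0.11 over all removals, as did Hba-a1 (-1.43 to 0.0775), Hba-a2 (-1.45 to 0.13) and Alas2 (-1.33 to 0.0385). Other named genes whose sign turned with a library left out were Il17a (-0.91 to 0.91), Ifng (-0.42 to 0.42), Foxp3 (-3.89 to 0.20), Il1b (-0.78 to 0.69), Tmem119 (-0.44 to 0.0479) and Mbp (-0.0854 to 0.59). Library size scaling turned Il17a (0.00681) and Ifng (0.00802), limma-voom turned Il17a (0.68), Ifng (0.12) and Il1b (0.0787), and quantile normalization turned Il17a (0.53), Ifng (0.0767) and Il1b (0.0314), and none of these genes passed under any of these settings. Over all alternatives 1807 values of named genes kept direction and side of the threshold, 19 turned, and 1 passed, the second Map2k7 identifier without P155 replicate 4 (limma adjusted p = 0.0324). The planned DESeq2 and edgeR fits were not run, and depth limits P155 replicate 5, with 7837 genes at 0 reads.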

Other observations

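The tests of Scr replicate 5, of the leukocyte share and of the number of jump genes by split, with its gap of 1, and the control for transcript number, were chosen only after the results were seen. Transcripts of neural tissue were abundant in libraries labelled as mononuclear cells. Mbp stood at 16.69 and 16.02 in Scr replicates 4 and 5 and at 16.75 and 16.46 in P155 replicates 4 and 5, above the invariant chain gene Cd74 in each library, and the neurofilament gene Nefh reached 15.57, 14.97, 15.82 and 15.63 in the same order. Haemoglobin genes took 0.292% of the reads in Scr replicate 4, 0.185% in Scr replicate 5, 0.094% in P155 replicate 4 and 0.265% in P155 replicate 5. Scr replicate 5 stood apart in 478 genes by more than 1 log2 unit from the other libraries, against 51 for Scr replicate 4, 76 for P155 replicate 4 and 146 for P155 replicate 5. Mitochondrial transcripts took 12.05% of its reads and 8.54% to 9.68% in the other libraries.

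Leukocyte lists were lower in P155 by camera with the preset correlation, and none kept that call with an estimated correlation (adjusted p = 0.599 to 0.613 with an estimated correlation) or with fry. Without Scr replicate 5, 7 of 14 leukocyte lists kept their call, with a T cell median of -0.24 against -0.73, while the neutrophil median of -1.36 became -2.23 without that library, -0.56 without Scr replicate 4 and -0.30 without P155 replicate 4, and since the split that ignores the treatment called 27 lists, the part of that library stays open. A lower share of leukocytes of all kinds was neither shown nor excluded. All 16 pan-leukocyte genes were lower in P155 on average, with a median of -0.75. Their mean was 0.10 and 0.65 in Scr replicates 4 and 5, and -0.11 and -0.64 in P155 replicates 4 and 5. The medians of MHC class II (-0.68) and type I interferon genes (-0.66) were of similar size, and a change apart from leukocyte RNA as a whole was not tested for them. Relative to the 16 genes, 4 of 4 lists differed by less than 2 SE, which is easily met with 2 libraries per group. B cell genes differed by -0.14 (SE 0.21), monocyte genes by 4.42e-04 (SE 0.28), T cell genes by 0.03 (SE 0.21) and neutrophil genes by -0.73 (SE 1.51). With a lower leukocyte share alone, other cell types should move alike. Oligodendrocyte genes and meningeal fibroblast markers differed by 3.38 SE. This was picked as the largest of 28 pairs, with SEs from 2 libraries per group, so it cannot decide and the question stays open. With 3 splits of the libraries a share under 0.05 cannot be reached, and 1 of the 3 splits, the labelled one, called as many as 31 lists, against 27 in the highest other, and an effect of P155 on the infiltrate stays open.

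Some genes jumped between library pairs by more than 1 log2 unit at a mean level above 8. There were 29 such genes between P155 and Scr, among them Sar1a, Zfp180 and E2f3, and 2 of the 3 splits had as many, with 62 when replicates numbered 4 were set against those numbered 5, a share that cannot fall under 0.05 with 3 splits. At gaps of 0.5, 1.5 and 2 the counts between P155 and Scr were 189, 12 and 3, against 330, 22 and 11 by number. With Scr replicate 4 and P155 replicate 5 set against the others they were 97, 8 and 2, and 22 at a gap of 1. Among all 113 jump genes of the 3 splits, the median share of 31-base words found in other genes was at percentile 60.6 of 10000 expression-matched random lists. A median cannot show whether some of these genes share sequence, and the 29 genes between P155 and Scr were not tested alone. The longest and shortest annotated transcripts of the 113 jump genes differed more than in matched genes, with a median log2 ratio of 3.37 at percentile 100. The ratio was also above the 95th percentile of 2.96 when lists were matched on transcript number. A switch between long and short transcripts, or how reads of such genes were counted, may contribute.

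P155 replicate 5 had fewer reads than the other libraries. After all libraries were thinned to its total, 100% of the 31 lists kept their call and direction, so the lower depth of this library does not account for the list calls.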
